A study of Mus musculus with 6 samples.

How the data were processed

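Poly(A) RNA from mouse ear skin was sequenced in 6 libraries, 3 from control pups and 3 from pups with a tamoxifen-induced endothelial knockout of Kdr (labelled ecko). The deposited table gives expected counts per gene, that is, estimated read numbers not scaled between libraries. The unit was read from the values, of which 10.1% to 10.4% per library are not whole numbers. The submitters' processing notes name HISAT2 2.2.1, Bowtie2 2.4.5, RSEM 1.3.1 and the genome build GRCm38.p6, without saying what each tool did. The annotation and the strand setting are not stated. The table holds 18404 genes, of which 18353 identifiers matched the RefSeq annotation of the same build, and 18248 are protein coding. Totals ran from 16987130 to 17979182 expected counts per library. Reads carry no molecular identifiers, so counting precision covers sampling of reads alone.

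The expected counts were rounded to whole numbers before testing. The single comparison, ecko minus control, used the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and glmQLFit was run with robust estimation. P-values were two-sided and adjusted by Benjamini-Hochberg over all 14920 genes tested, with a threshold of 0.05. Log2 fold changes are given with a standard error (SE) derived from the test, as the absolute log2 fold change divided by the square root of its F statistic. CPM is the count scaled to a common library size after TMM and is given as mean ± SD over 3 libraries. The smallest p of an exact permutation test of 3 against 3 libraries is 0.1, so no single value was tested that way.

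Lists of cell type markers and pathway genes were fixed before the data were examined, and the 26 with at least 5 tested members were run. For each list the members past the edgeR test were counted, adjusted over all genes and adjusted over the list alone. The lists were also tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 26 lists. Kdr was left out of every list in that test because it is the deleted gene. Camera with an estimated correlation and fry were alternatives.

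The genes named follow a rule fixed before the data were examined. It takes Kdr with its receptor and ligand family. It takes up to 10 genes past the threshold in each direction, with a mean count of at least 20 and no overlap between groups. Where fewer than 3 genes passed, it takes the 5 smallest unadjusted p in that direction, given as not past the threshold. It takes the 4 members of each list with the smallest unadjusted p, and the Y-linked genes as a check of the samples. Prox1, Lyve1 and Runx1 fall outside the rule and were chosen after their values were seen.

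Alternatives for the gene test were DESeq2 size factors, no low-count filter, a filter of at least 1 CPM in at least 3 libraries, the Wald test of DESeq2 1.42.0 and limma-voom. Further ones were a replicate block, leaving out each library in turn, leaving out the 20 most abundant genes, the skeletal muscle level as a covariate, and glmQLFit without robust estimation. The set tests were also run with a prior count of 0.5. The level of Y-linked genes as a covariate was added after the data were seen, as were the list counts under each alternative and 10 further gene lists used in the closing section. Bootstrap intervals of list medians are 95% intervals from 10000 draws of genes. They take correlated genes as independent and hold no spread between libraries.

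The gene test was tested on simulated data with the dispersions and depths of these libraries, in which 200 genes were changed. edgeR recovered 61.2% of genes changed 1.5-fold, 91% of those changed 2-fold and 98.5% of those changed 4-fold, with 9 false calls. With no gene changed it made 2 calls. DESeq2 recovered 62.7%, 89.6% and 97% with 21 false calls, and made 7 calls with no gene changed. Camera found the 1 list that was shifted and called 0 others. The simulated libraries varied gene by gene and held no shared differences in tissue content.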

Results

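RNA from the ear skin of mouse pups at postnatal day 3 was sequenced in 3 control libraries and 3 libraries from pups with an induced endothelial knockout of Kdr (ecko). Kdr encodes VEGFR2, the main signalling receptor for VEGF-A on endothelial cells. Tamoxifen is recorded for the pups of both groups, from postnatal day 1 at 60 µg per day. This was 48 h before collection, a time given in the name of the series. The sample titles do not give the genotype of the controls. The series addresses whether reduced VEGFR2 in endothelium moves gene expression away from lymphatic and toward blood-forming programs. Each library held 16987130 to 17979182 expected counts, and the most abundant transcript in all 6 was Col3a1, with 1.53% to 1.74% of the counts. The labels do not say whether the replicates are separate animals or litters, so the p-values measure the spread between these samples.

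Each group held 1 library almost without Y-linked reads. Ddx3y had 4 counts in control 2 and 6 in ecko 3, against 1445 to 1641 in the other 4 libraries. Control 3 had the lowest mean level of skeletal muscle genes, 6.07 log2 CPM, against 6.51 to 6.87 in the other libraries. Pairs of libraries were also compared by chi-square per gene, over genes with a mean count of at least 20. It was 13.24 to 19.76 in the pairs with control 3. In the other pairs it ran from 4.18 (control 1 with ecko 2) to 11.47 (control 2 with ecko 1).

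Kdr transcripts fell to 0.242 of the control level. The gene (Entrez 16542, chromosome 5, 75932827 to 75979072 in GRCm38.p6) had 1599, 1860 and 1337 counts in the controls and 348, 431 and 370 in ecko. These are 90.0 ± 12.9 CPM (SD, n = 3) against 21.7 ± 2.4 CPM (SD, n = 3), a log2 fold change of -2.05 ± 0.12 (SE), with an edgeR adjusted p of 0.0002. Flt1, the VEGFR1 gene, was lower in all 3 ecko libraries than in any control, with 21.2 ± 1.44 against 25.3 ± 1.61 CPM, and did not pass (log2 fold change -0.25, adjusted p 0.513). Flt4, the VEGFR3 gene of lymphatic endothelium, had a log2 fold change of -0.10, and the co-receptors Nrp1 and Nrp2 had -0.12 and -0.07. None of these 3 passed the test. The ligand Vegfd had 0.33 ± 0.16 (adjusted p 0.573), while Vegfa, Vegfb, Vegfc and Pgf lay between -0.01 and 0.12 with groups that overlapped.

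**Figure D1:**
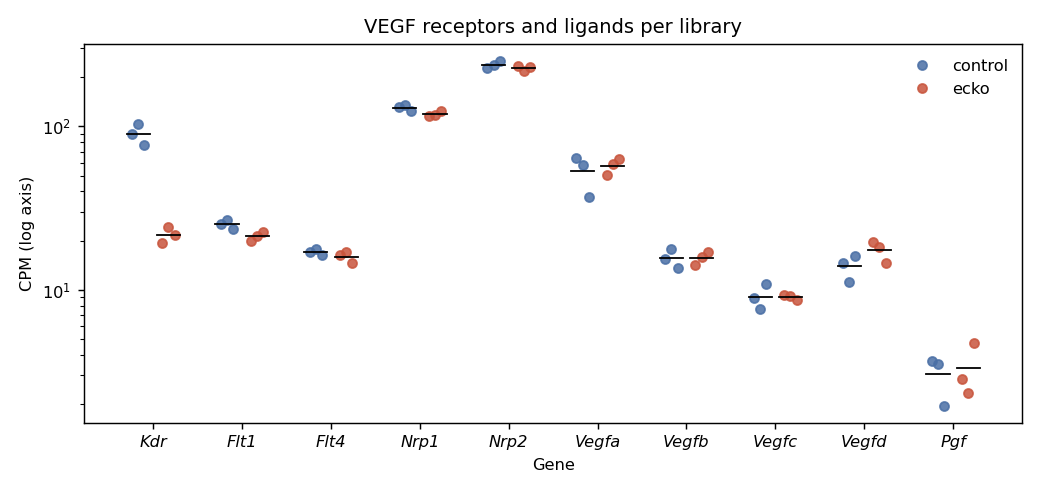
CPM (log axis) of Kdr and the other VEGF receptors and ligands in each of the 3 control and 3 ecko libraries; each point is 1 library and each black bar a group mean. Kdr had means of 90.0 and 21.7 CPM, and Flt1 was the other gene of the family whose groups did not overlap.

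Over all 14920 genes tested, edgeR called 1 gene lower, Kdr, and 0 genes higher. The next smallest adjusted p was 0.1496. At an unadjusted p under 0.05 there were 734 genes higher and 611 lower, where 746 in all are expected by chance. DESeq2 called 86 genes higher and 26 lower, and limma-voom called 0 higher and 1 lower. Without ecko 3 edgeR called 2 genes higher. The genes closest to the edgeR threshold on the higher side were Mpeg1, a macrophage pore-forming protein (log2 fold change 0.59), and 4 interferon-induced genes. These were Irgm1 (0.83), the ubiquitin-like modifier Isg15 (1.304), Ifi44 (1.55) and Rnf213 (0.91), each with an adjusted p of 0.1496. On the lower side stood the fatty acid synthase gene Fasn (-0.48), the HDL receptor gene Scarb1 (-0.41), Depp1 (-0.98), the lipogenic regulator Thrsp (-1.18) and the metalloproteinase inhibitor Timp4 (-1.06). Their adjusted p ran from 0.1496 to 0.1984. All 10 genes passed with DESeq2, and their groups did not overlap. As they were picked by a small edgeR p in the same libraries, neither is separate support.

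Type I interferon response genes were higher in ecko as a group. All 27 tested members had a higher mean in ecko, the median log2 fold change was 0.995 (1.99-fold), and in 24 members the groups did not overlap, where chance gives 10% in both directions together and the share over all genes was 15.7% (1126 higher, 1210 lower). Adjusted over the list alone 25 members rose, and adjusted over all genes 0 passed. Isg15 rose from 4.22 ± 0.92 to 10.4 ± 2.33 CPM (SD, n = 3), and Ifi44 from 1.97 ± 0.65 to 5.79 ± 1.03 CPM. Zbp1, a sensor of Z-form nucleic acids, rose 2.76-fold from 2.97 to 8.20 CPM, and the oligoadenylate synthetase gene Oas3 rose 2.70-fold from 1.79 to 4.82 CPM. Each of these 4 had an adjusted p of 0.000763 over the list alone. Cxcl10, an interferon-induced chemokine in the cytokine and adhesion list, rose 4.20-fold, the 1 member of that list to rise adjusted over the list alone. Its counts were 17, 18 and 17 in the controls and 121, 51 and 47 in ecko. By camera the interferon list had an adjusted p of 5.13e-26, and an adjusted p = 0.842 with an estimated correlation.

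Genes of fat storage and lipid synthesis were lower. In the adipocyte and lipid list 21 of 24 members had a lower mean in ecko, with a median log2 fold change of -0.20. Adjusted over the list alone 9 members fell and 0 rose, and adjusted over all genes 0 passed. Fasn fell from 243 ± 9.72 to 174 ± 14.4 CPM (SD, n = 3). Dgat2, the enzyme of the last step of triglyceride synthesis, fell from 181 ± 18.2 to 129 ± 15.5 CPM, Acaca, which makes malonyl-CoA, from 122 ± 7.33 to 96.9 ± 7.33 CPM, and Thrsp from 9.70 ± 1.20 to 4.28 ± 1.34 CPM. The count that fell was 4 without control 2 and also without ecko 3, and 5 without ecko 1, and the median was -0.35 without control 3. The camera adjusted p was 2.86e-07, with adjusted p = 0.842 with an estimated correlation.

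The median of the pan-endothelial genes was slightly lower in ecko, and that of the lymphatic genes was near 0. Of 34 pan-endothelial members 28 had a lower mean in ecko, with a median log2 fold change of -0.17 (0.890-fold). In 13 the groups did not overlap, lower in ecko, and in 1, Bmx, higher. Chance gives 10% in both directions together, and the share over all genes was 15.7%. Gpihbp1, which carries lipoprotein lipase across capillary endothelium, fell from 21.4 ± 2.03 to 14.2 ± 1.46 CPM (SD, n = 3) and was the 1 member past the test adjusted over the list alone (adjusted p 0.0133). Arhgef15, Robo4 and Plvap had log2 fold changes of -0.49, -0.29 and -0.21, with adjusted p of 0.0793 over the list alone. Among 30 tip cell and VEGF-Notch response genes the median was -0.09, and Igfbp3 fell adjusted over the list alone (-0.27 ± 0.06, adjusted p 0.0248). The Notch ligand gene Dll4 (-0.50) and the tip cell genes Esm1 (-0.83) and Apln (-0.45) had groups without overlap and did not pass. The camera adjusted p was 6.11e-07 for the pan-endothelial and 0.0103 for the tip cell list, and for both lists adjusted p = 0.842 with an estimated correlation. Without control 2 the tip cell list had a camera adjusted p of 0.0878, and without ecko 2 of 0.0620.

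The lymphatic and hematopoietic lists were measured in RNA of ear skin, so each median covers every cell type that expresses the members. A shift within endothelial cells alone was not measured and could go unseen. The 23 lymphatic endothelial genes had a median log2 fold change of -0.01, with 11 higher and 12 lower. Adjusted over the list alone 0 passed, and the camera adjusted p was 0.948. The chemokine gene Ccl21a had 0.31 ± 0.18 and Mmrn1 had -0.21 ± 0.12. Prox1, the transcription factor of lymphatic identity, had 10.8 ± 0.78 CPM in ecko and 9.21 ± 3.00 CPM in the controls (SD, n = 3; adjusted p 0.778), and Lyve1, a lymphatic and macrophage receptor, 56.7 ± 8.89 and 57.4 ± 5.06 CPM (adjusted p 0.975).

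Among 32 hematopoietic transcription factor and progenitor genes 19 had a higher mean in ecko. The median log2 fold change was 0.06, 0 members passed adjusted over the list alone, and the camera adjusted p was 0.201. Ptprc, the pan-leukocyte CD45 gene, had 0.37 ± 0.11, the leukocyte GTPase gene Rac2 0.25 ± 0.10 and Mecom -0.39 ± 0.15. Runx1, a regulator of blood cell emergence, had 50.2 ± 0.82 CPM in ecko and 48.4 ± 3.79 CPM in the controls (adjusted p 0.859). Erythroid genes had a median of -0.14 with 16 of 19 lower (camera adjusted p 0.0765, or 1.48e-07 without control 3 and 0.488 without control 1; it also passed without ecko 3), and megakaryocyte and platelet genes -0.02 (0.482). Gng11, a G-protein subunit in the platelet list, fell adjusted over the list alone (-0.47 ± 0.11).

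Macrophage and monocyte genes were higher by a small amount. Of 29 members 27 had a higher mean in ecko, with a median log2 fold change of 0.18. Adjusted over the list alone 3 rose: the Fc receptor gene Fcgr1 (from 10.8 ± 2.47 to 17.5 ± 2.11 CPM; SD, n = 3), the phosphatidylserine receptor gene Timd4 (1.75 ± 0.18 to 2.95 ± 0.07 CPM) and the lysosomal marker Cd68 (24.5 ± 0.14 to 30.1 ± 1.22 CPM). None of the list passed without control 2, without ecko 1, without ecko 2 or without ecko 3, and 6 rose without control 1. The camera adjusted p was 9.26e-07, with adjusted p = 0.842 with an estimated correlation. A later list of 15 abundant macrophage genes left out interferon-induced ones and held Cd68 but not Fcgr1 or Timd4. All 15 had a higher mean in ecko, with a median of 0.143, and 0 passed adjusted over the list alone. Its unadjusted camera p was 0.000236, and 0.1815 with an estimated correlation. Mast cell genes had a median of 0.13 and 0 members past the test adjusted over the list alone. Their camera adjusted p was 0.0288, with adjusted p = 0.842 with an estimated correlation, 0.470 without control 2 and 0.0701 without ecko 3.

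In the neutrophil list the granule peptide gene Camp fell (counts of 15, 20 and 16 in the controls and 2, 7 and 4 in ecko) adjusted over the list alone. The receptor genes Csf3r and Cxcr2 had log2 fold changes of 1.15 ± 0.33 and 1.41 ± 0.45 and an adjusted p of 0.0542 over the list alone, and the list had a camera adjusted p of 0.149. Ndufa4l2, in the pericyte list, rose from 32.8 ± 5.31 to 52.3 ± 3.34 CPM and the heat shock gene Hspa1b fell from 82.4 ± 2.54 to 65.8 ± 3.71 CPM (SD, n = 3), both adjusted over their lists alone. Neither list passed by camera, with adjusted p of 0.589 for the pericyte and 0.0509 for the heat shock list. The hypoxia list had a median of 0.07 (0.0509) and the cell cycle list 0.10 (0.0559), each with 0 members past the test adjusted over the list alone. Of 32 cell cycle members, 9 had groups without overlap higher in ecko and 4 lower, where the share over all genes was 15.7%. Cenpe (0.44) and Ccnb1 (0.18) were among the higher ones, and Mcm3 (-0.27) and Mcm4 (-0.20) among the lower. Medians of the 2 keratinocyte lists and of the hair follicle, fibroblast, melanocyte, Schwann cell, cartilage and skeletal muscle lists lay between -0.08 and 0.06, and none of these passed by camera. Nor did the lymphoid list (median 0.21, camera adjusted p 0.454), the cytokine and adhesion list (0.06, 0.687) or the VEGF receptors and ligands without Kdr (-0.01, 0.482). Several lists not called here passed by camera with 1 library left out. Skeletal muscle ran from 1.91e-05 to 0.707, and was lower in ecko without control 3 (0.00766). Differentiated keratinocyte ran from 0.000111 to 0.581, hypoxia from 0.00214 to 0.324 and cell cycle from 0.000949 to 0.788.

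**Figure D2:**
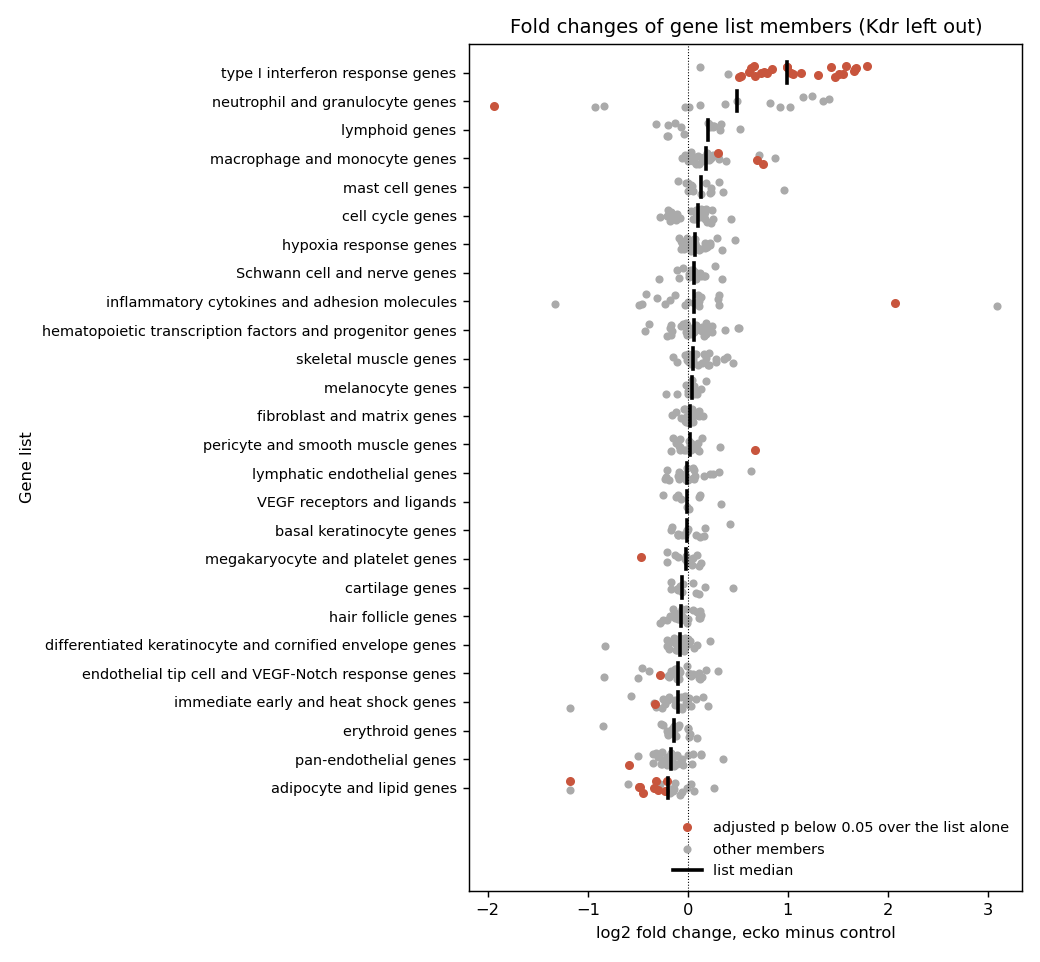
Log2 fold change, ecko minus control, of each tested member of 26 gene lists, with Kdr left out. Red points passed adjusted over the list alone, grey points did not, and black bars are list medians, which ran from -0.20 for adipocyte and lipid genes to 0.995 for type I interferon response genes.

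Camera with the preset correlation called 6 of the 26 lists for ecko against control. It called 14 without control 1 and 10 without control 3 or without ecko 1, and 5 to 13 lists for the other 9 ways of splitting the 6 libraries into groups of 3. With an estimated correlation and with fry 0 lists passed.

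**Figure D3:**
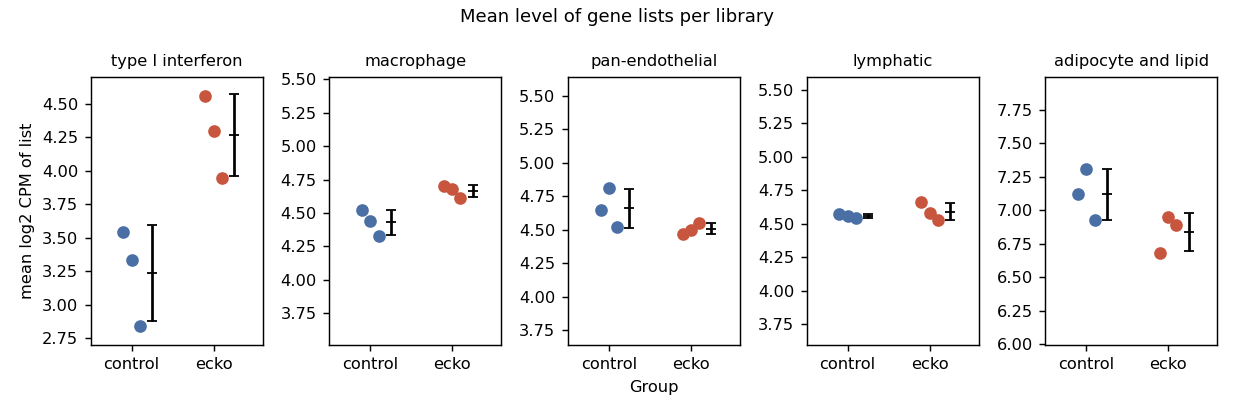
Mean log2 CPM of the members of 5 gene lists in each library, with the group mean and SD (n = 3) beside the points; the vertical axes cover equal ranges. The interferon means were 2.84 to 3.54 in the controls and 3.95 to 4.56 in ecko, and the lymphatic means were 4.54 to 4.57 and 4.53 to 4.66.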

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

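The Y-linked covariate, the member counts under each alternative and the choice of Prox1, Lyve1 and Runx1 came after the data were seen; the other alternatives were set before the data were examined. Kdr stayed past the threshold under every alternative run, with log2 fold changes of -1.945 to -2.144 when 1 library was left out. The interferon median stayed between 0.79 (without ecko 1) and 1.18 (without ecko 3), with 24 to 26 members past the test adjusted over the list alone under all alternatives. The lipid median ran from -0.16 (without control 2) to -0.35 (without control 3).

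The number of genes called depended on the model, with Kdr among the lower genes each time. DESeq2 called 86 higher and 26 lower, the edgeR fit with a replicate block 88 and 10, and the skeletal muscle covariate 60 and 8. DESeq2 and the replicate block shared 71 higher and 10 lower genes, and all 3 models shared 51 and 7. Whether the replicate numbers pair the samples is not settled by these values. Deviations from the group mean correlated at 0.113, -0.148 and 0.003 for equal numbers, across genes, and at 0.186 for control 2 with ecko 3. Yet the interferon means fell from replicate 1 to 3 in both groups (3.54, 3.33 and 2.84 in the controls, 4.56, 4.30 and 3.95 log2 CPM in ecko). The macrophage, lymphatic and muscle means shared that order, and the pan-endothelial, lipid and erythroid means did not. These values therefore give no ground to prefer the block result to the unblocked one, nor to set it aside. The Y-linked covariate gave 1 gene higher. Leaving out 1 library gave 0 to 2 higher, with 2 without ecko 3. The cause of these differences was not tested.

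Macrophage members past the test adjusted over the list alone numbered 6 with the replicate block, 5 with the muscle covariate, 1 with the Y-linked covariate and 0 (without control 2 or any 1 ecko library) to 6 (without control 1) with 1 library left out. Lipid members numbered 4 (without control 2 or ecko 3) to 12 (without control 3). Camera called 0 lists with an estimated correlation, 10 with the filter of at least 1 CPM, 5 (without ecko 2) to 14 (without control 1) with 1 library left out, and fry called 0. The 6 called lists had an adjusted p of 0.842 with an estimated correlation. Unadjusted, that camera p was 0.0637 for the interferon, 0.0796 for the macrophage and 0.106 for the lipid list. It was 0.193 for the pan-endothelial, 0.194 for the tip cell and 0.198 for the mast cell list. With fry the adjusted p was 0.254 for the interferon and macrophage lists, 0.616 for the lipid list and 0.715 for the pan-endothelial, tip cell and mast cell lists. With 1 library left out the tip cell list ran from 0.000357 to 0.0878 and the mast cell list from 0.00212 to 0.470. The skeletal muscle list, not called with all libraries, ran from 1.91e-05 to 0.707 and turned lower in ecko without control 3, with an adjusted p of 0.00766. The erythroid list, also not called with all libraries, ran from 1.48e-07 (without control 3) to 0.488 (without control 1). The neutrophil, lymphoid, fibroblast, differentiated keratinocyte, hair follicle, Schwann cell, hypoxia, cell cycle and heat shock lists each passed with at least 1 library left out, with lowest adjusted p of 0.000111 to 0.0374.

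Some genes that were not called changed sign around 0. Vegfb was -0.007 with the muscle covariate and -0.073 to 0.112 with 1 library left out. Vegfc was 0.006 with limma-voom, 0.001 with the replicate block, 0.046 with the muscle covariate and -0.125 to 0.134 with 1 library left out. With 1 library left out Vegfa ran from -0.080 to 0.269, Pgf from -0.235 to 0.307, Prox1 from -0.017 to 0.390, Lyve1 from -0.146 to 0.074 and Runx1 from -0.011 to 0.097. In simulated libraries of this depth, edgeR recovered 61.2% of genes changed 1.5-fold, and smaller changes were not simulated. Those libraries held no shared differences in tissue content, so the share cannot be carried over to the real data. There Isg15, at 2.47-fold, and Cxcl10, at 4.20-fold, did not pass edgeR (adjusted p 0.1496 and 0.2209).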

Other observations

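The gene families, the 10 further lists and the genes named from them here were chosen after the results were seen. The macrophage, sex, adipocyte, sterol, feeding, glucocorticoid, endothelial loss and lymphatic tests, or the bars they had to meet, were also set after the values they use had been seen, and the other tests before. Means were also higher in ecko in interferon-related families outside the fixed list, on which no set test was run. All 9 guanylate-binding protein genes tested had a higher mean in ecko (median log2 fold change 0.87, groups without overlap in 8), as had all 8 Schlafen genes (0.68, 8), all 6 immunity-related GTPase genes (1.10, 6), all 10 genes of the p200 family of DNA sensors (1.12, 7) and all 3 Trim30 genes (0.97, 3). Chance gives 10% without overlap and the share over all genes was 15.7%. DESeq2 called 6 of the guanylate-binding protein, 2 of the Schlafen, 4 of the GTPase, 5 of the p200 and 2 of the Trim30 genes higher, and edgeR called none. Of the 86 genes DESeq2 called higher, 22 were among the 27 members of the interferon list (Fisher's exact test, one-sided, p = 7.07e-47, background 15744 genes, which are not independent). Of the 26 called lower, 5 were among the 24 members of the lipid list (p = 3.4e-10, same exact test). Of 9 interferon genes listed, 4 are in the table: Ifnb1, Ifne, Ifnk and Ifng had 0 to 3 counts per library, so a difference in these was not detectable at this depth, and the other 5 have no values. A list of mature neutrophil genes, drawn up after its genes had been seen and therefore no test of them, had 5 of 5 tested members higher in ecko with a median of 1.24, and it left out Camp and other members of the fixed list that were lower. Its camera adjusted p over the 10 further lists was 0.00128, its camera p 0.192 with an estimated correlation, and another split of the libraries gave an absolute median of 1.43.

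Sterol synthesis genes were lower in ecko as well. All 21 tested cholesterol synthesis genes had a lower mean in ecko, and 6 fell adjusted over the list alone, among them the squalene epoxidase gene Sqle (-0.34 ± 0.09, SE), Insig1 (-0.31 ± 0.08) and Mvk (-0.32 ± 0.08). In a fatty acid and NADPH synthesis list that left out the genes already seen, 14 of 15 were lower (median -0.15) and 3 fell adjusted over the list alone, among them the desaturase gene Scd2 (-0.37 ± 0.11). With an estimated correlation the camera p, unadjusted, was 0.0738 for the sterol list and 0.0510 for the fatty acid list. The absolute sterol median was 0.194 in the real split of the libraries and reached 0.188 in another. Pdk4, a switch from glucose to fat use in fasting, had a log2 fold change of 0.90 ± 0.33 and did not pass.

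The interferon rise was set against 5 explanations. More macrophages in ecko skin would raise their abundant genes as much, yet 15 such genes, chosen to leave out interferon-induced ones, had a median of 0.143 (95% interval 0.049 to 0.180) against 0.995. Reads split in fractions between paralogs are argued against by the 23 members with exactly whole counts in every library. Their median was 0.845 (0.675 to 1.304). Shared reads assigned wholly to 1 paralog would not show in these values. Pup sex is argued against by the balance of the groups, each with 1 library without Y-linked reads. It is also argued against by a median difference of 1.169 (0.899 to 1.463) among the 4 libraries with such reads. Between the 2 without, the difference was 0.556, below that interval. The intervals here come from draws of genes, which are correlated, and hold no spread between libraries. A single library is argued against by medians of at least 0.792 with any 1 left out. Interferon gamma as the inducer cannot be told apart from type I interferon, since MHC class II genes had a median of -0.073 (-0.174 to 0.178), an interval that reaches the class I median of 0.125. More neutrophils in ecko skin stay open as a contributor and were not tested. Csf3r had 68, 52 and 46 counts in the controls and 181, 121 and 67 in ecko, so control 1 and ecko 3 were level, while the interferon means were 3.54 in control 1 and 3.95 log2 CPM in ecko 3 and the neutrophil gene Camp fell. A response to type I interferon in ecko skin remains a hypothesis. Differences between litters, in exposure to infection or in genotype other than the loss of Kdr were not tested.

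For the lower lipid genes, fewer adipocytes cannot be told apart from lower lipid synthesis. Adipocyte identity genes had a median of -0.181 and lipogenic enzymes -0.334, and the exact permutation test over genes gave p = 0.355. Lower sterol synthesis, with a list median of -0.194 (-0.301 to -0.158), stays open because its camera p with an estimated correlation was 0.0738. Reduced feeding of ecko pups stays open too, since 18 of 24 genes of the FOXO and fasting response were higher with a median of 0.168 (0.063 to 0.255) and a camera p of 0.212 with an estimated correlation. Glucocorticoid stress stays open as well: its 12 response genes had a median of -0.044 (-0.080 to 0.024), but 4 were higher and 8 lower, from -0.73 to 0.90, a spread wider than the lipid change. That spread came from Per1 (-0.73), Pdk4 (0.90) and Lcn2 (0.83), and the other members lay between -0.10 and 0.04. Per1 had 1795 counts in control 3 against 484 and 485 in controls 1 and 2, and Pdk4 is also in the fasting list.

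A loss of endothelial cells does not account for the fall of Kdr. Pan-endothelial genes had a median of -0.169 (-0.229 to -0.113), and the 95% bound of Kdr nearest to 0, by a normal approximation from its SE, was -1.815. A smaller share of all endothelial cells, lymphatic ones included, cannot be told apart from a change in blood vessel cells alone. The lymphatic median was -0.008 (permutation test over genes against the pan-endothelial list, p = 0.00492, in which correlated genes count as independent), but its members ran from -0.23 to 0.63 and the gap of 0.161 lay within their SD of 0.196. Lower expression per cell was not tested.

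The 6 libraries split into groups of 3 in 10 ways, too few for a share under 0.05. edgeR called 1 gene lower in the real split and 0 in any other, so 1 split reached that count, and all 10 splits reached its 0 genes higher. DESeq2 called 112 genes in the real split and at most 35 in another, and the interferon median was 0.995 against at most 0.737, so in each case 1 split reached the real value. Camera called 6 lists in the real split and up to 13 in another, and 9 splits reached 6, so a camera call at the preset correlation was not specific to the real split. Every other split still holds 2 libraries of 1 genotype against 1, and the called lists had estimated correlations of 0.141 to 0.848 against the preset 0.01. The interferon list was itself called by camera in 6 of the other 9 splits. Among the lists called, the real split gave the highest absolute median of the 10 for the interferon, pan-endothelial, macrophage and mast cell lists. Outside the interferon list the margins were narrow. They were 0.169 against 0.159 for the pan-endothelial, 0.18 against 0.169 for the macrophage and 0.13 against 0.111 for the mast cell list. The macrophage list without interferon-induced genes had 0.143 in the real split, and another reached 0.186. The lipid list reached 0.214 in another split against 0.196 in the real one. The tip cell median was reached in another split as well.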
